A study of Mus musculus with 2 samples.

How the data were processed

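Single-cell RNA libraries of mouse cochlea at postnatal day 42 were analysed from their deposited count matrices, 1 library for the control group and 1 for Plp1_TAT_DTR, both of the C57BL/6 strain per the labels. The sources are described in the labels as mixtures of many cochlear cell types, and no sort is named. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 3.0.2 per the file headers, on genome build mm10 per the submitters' processing notes. Those notes also name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.1.0, StringTie 1.3.5 and HTSeq 0.10.0 without saying for which data, and the labels' protocols also describe full-length libraries of single inner hair cells from other mice, which were not analysed here. The barcodes had been filtered before deposit, since the lowest held 501 UMIs in each library. The feature list has 21860 entries, tdTomato among them, of which 17657 had a UMI, and 21817 identifiers were matched to the GENCODE vM21 annotation, build mm10, for gene positions, counted from 1.

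Barcodes with under 500 genes or over 20% mitochondrial UMIs were removed, which concerned 90 and 345 control barcodes and 241 and 572 Plp1_TAT_DTR barcodes. Doublets were called per library with Scrublet in scanpy 1.11.5, 51 in control (1.18%) and 120 in Plp1_TAT_DTR (2.17%), and removed, leaving 3890 and 4679 cells. The kept cells of both libraries were clustered together, without batch correction, on UMIs scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2). The genes of the comparison lists, mitochondrial genes and sex-linked genes were left out of the clustering. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used with seed 0.

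Clusters were named from markers of 28 classes fixed before the data were examined. A cluster took a class's name when at least 3 of its markers were among its 60 leading genes by fold, each in at least 20% of its cells, with at least 2 more than the next class, and when no other class had more markers among its 10 leading genes. A cluster far shallower than its library stayed unnamed unless a marker was among those 10 genes. This rule was set after the files were seen, and left 19 of 35 clusters unnamed. Hair-cell-like cells were clustered again on 500 variable genes, 10 components, 5 neighbours and resolution 0.5, and a subcluster was named from markers at or above 100 CPM. The subcluster settings and their naming rule were changed several times after the subclusters were seen, and stricter versions left most of these cells unnamed; the comparisons of all hair-cell-like cells do not use them. The classes are rebuilt from the counts, so they can differ from those of the study.

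Cells are not replicates, so UMIs were summed per class and library and no test across samples was made, as 1 library per group gives none. Levels are CPM of the summed UMIs with exact Poisson intervals, ratios of CPM have exact conditional binomial intervals, and shares of cells have exact Clopper-Pearson intervals, all at 95% and for counting error only. Log2 ratios have 0.5 UMIs added on each side. Where a side held 0 UMIs the ratio is given as a bound against a floor of 3 UMIs over that class, and list medians are given also with such genes at that bound. Genes with at least 10 summed UMIs over both sides entered a comparison. Each list's median log2 ratio was set against 10000 random lists of the same size matched on expression, as a description of these libraries.

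The comparisons were the shares of each class, hair cells in each library, the induced genes by class, hair cells of Plp1_TAT_DTR against inner border and phalangeal cells of control and of the same library, inner against outer hair cell genes, hair cells between the libraries, inner border and phalangeal cells between the libraries, and other classes with at least 100 cells in both. Clusters 1, 2, 3, 6 and 7, which had that many cells and no name, were compared by number, after the files were seen. Hair cells were compared between libraries because the control reached the 10 cells required. The gene lists were fixed at the same time as the markers: inner hair cell genes, outer hair cell genes, hair cell transcription factors, mechanotransduction, hair bundle, ribbon synapse and exocytosis, hair cell channels and efferent receptor, calcium buffers, inner border and phalangeal cell genes, Notch pathway, tectorial and otic matrix, myelin, interferon response and MHC class I, inflammatory signals, phagocytic macrophage genes, dissociation and immediate early genes, p53 targets, fibrosis and matrix, nuclear oxidative phosphorylation and sex-linked genes. Atp5o, whose symbol was not matched, and Xist were missing from the features. In each comparison the named genes were up to 4 per list with the most UMIs, the 10 higher and 10 lower whose interval lay farthest from a ratio of 1, without mitochondrial, ribosomal protein and haemoglobin genes, and Atoh1, Tbx2, Plp1, Slc17a8, Slc26a5, Ocm and Otof. tdTomato was added after the files were seen.

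The ratios with their intervals and the list medians were tested on simulated counts with 200 changed genes. The values below do not cover the filters, doublet calls, clustering or naming. The intervals are for counting error only, so their coverage does not bear on variation between cells or animals. For hair cells between the libraries, over 10389 genes, 88% of the 2-fold increases and 66% of the 2-fold decreases had an interval that excluded 1, as did 100% and 90% of those of 4-fold, and the intervals covered the simulated ratio for 96.7% of genes. For hair cells against inner border and phalangeal cells of control, over 10938 genes, the values were 84%, 70%, 100% and 94%, and for inner border and phalangeal cells between the libraries, over 10493 genes, 82%, 74%, 100% and 94%. Alternatives covered the gene minimum, the mitochondrial limit, doublets, the resolution, list genes in the clustering, a gate of 3 hair cell markers, the scaling of CPM, equal weight per cell and the UMI minimum. A gate of 8 markers, inner-hair-like cells alone, a limit of 60000 UMIs per hair cell and the outer hair cell list without Ocm were added after the data were seen.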

Results

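Gene expression was measured in single cells of the mouse cochlea at postnatal day 42, in 1 droplet library per group, so no difference below has a replicate check. The control library came from Plp1-CreER+; Ai9/+ mice given tamoxifen at postnatal days 0 and 1. Plp1-CreER is a tamoxifen-activated recombinase made where Plp1 is expressed, in glia and in the supporting cells that surround inner hair cells, and Ai9 is a reporter that makes tdTomato after recombination. The library called Plp1_TAT_DTR came from mice given tamoxifen on the same days, diphtheria toxin at day 2, which kills cells that carry its receptor, and trimethoprim at days 3 and 4, a drug used to stabilise proteins fused to a destabilising domain. The study asks whether supporting cells can become inner hair cells after damage when Atoh1, the transcription factor that starts hair cell fate, and Tbx2, a transcription factor of inner hair cells, are induced together. The files held 4330 control barcodes with 58236603 UMIs (unique molecular identifiers, counted transcripts) and 5536 Plp1_TAT_DTR barcodes with 60227504 UMIs, at medians of 5772 and 6478.5 UMIs per barcode. After the filters 3890 control cells and 4679 Plp1_TAT_DTR cells were kept. All intervals are at 95% and cover counting error only, and CPM is a gene's count in the summed cells of a class, scaled to their total.

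The cochlear classes of both libraries included glia, sensory epithelium, neurons, stria and vessels, in different proportions. Myelinating-Schwann-like cells, led by Ncmap, Mpz and Mbp, made up 28.1% of control cells (exact binomial interval 26.7 to 29.5) and 12.99% of Plp1_TAT_DTR cells (12.04 to 13.99). Spiral-ganglion-neuron-like cells, with Nefl, Nefm and Snap25 among their leading genes, made up 6.68% (5.92 to 7.51) and 1.73% (1.38 to 2.15). The opposite order was seen for marginal-like cells of the stria, led by Kcne1 and Kcnq1, at 0.0771% (0.0159 to 0.225) and 1.05% (0.776 to 1.38). The same order was seen for Reissner's-membrane-like cells at 0.540% (0.334 to 0.824) and 1.97% (1.59 to 2.41), and for melanocyte-like cells with Dct and Tyr at 0.334% (0.178 to 0.571) and 1.45% (1.13 to 1.84). Inner-border/phalangeal-like cells, the supporting cells beside inner hair cells, were close in share, at 1.85% (1.45 to 2.33) and 2.14% (1.74 to 2.59). Slc1a3, Sox2, Gjb2, Gjb6, Otog and Otogl were among their leading genes. Fibroblast-like cells were 42 in control and 0 of 4679 in Plp1_TAT_DTR, with an upper limit of 0.0788%. Clusters without a name held 49.6% of control cells (48.0 to 51.1) and 63.6% of Plp1_TAT_DTR cells (62.2 to 65.0). Dissection and dissociation can set such shares, and with 1 library per group a cluster mostly of 1 library may reflect that library.

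Hair-cell-like cells were a larger part of the Plp1_TAT_DTR library than of the control library. The class was led by Otof, a vesicle fusion protein of hair cells, the calcium buffer Ocm, Pcp4, Slc17a8, the glutamate transporter of inner hair cells, and Cabp2. It held 10 of 3890 control cells, 0.257% (0.123 to 0.472), and 57 of 4679 Plp1_TAT_DTR cells, 1.22% (0.924 to 1.58). Among hair-cell-like, inner-border/phalangeal-like and Deiters/pillar-like cells together, hair cells were 10 of 94 in control, 10.6% (5.22 to 18.7), and 57 of 173 in Plp1_TAT_DTR, 32.9% (26.0 to 40.5). By subcluster, all 10 control cells and 49 Plp1_TAT_DTR cells were inner-hair-like, with Slc17a8, Slc7a14, Dnajc5b, Atp2a3 and Calb2. A further 8 Plp1_TAT_DTR cells were outer-hair-like, with Slc26a5, the motor protein of outer hair cells, Ocm, Chrna10, Lbh and Strip2. Control hair cells were deeper, at a median of 48902.5 UMIs against 27248. No outer-hair-like cell passed the filters in control (0 of 3890, upper limit 0.0948%). The limit on mitochondrial share had removed 3 control barcodes with 407 Ocm UMIs and 5 Slc26a5 UMIs, and without that limit 2 outer-hair-like cells appeared.

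**Figure D1:**
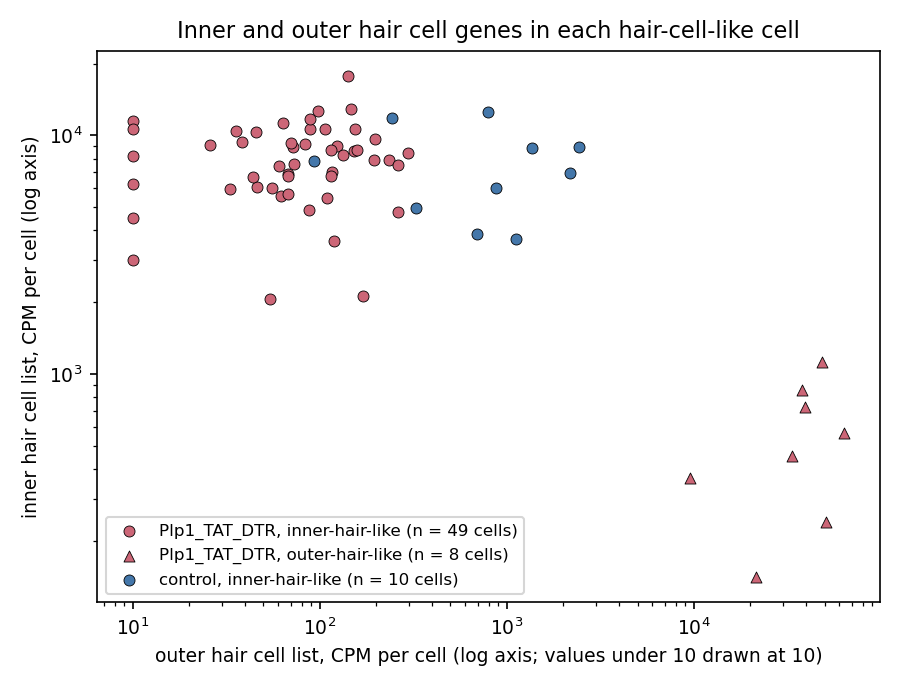
Each point is a hair-cell-like cell, placed by its CPM of the outer hair cell list (horizontal log axis) and of the inner hair cell list (vertical log axis), with colour for the library and shape for the subclass. The subclasses were named from genes of these lists. The 8 outer-hair-like cells of Plp1_TAT_DTR lie apart from its 49 inner-hair-like cells, and the 10 control cells, with a median outer-list level of 834 CPM, lie to the right of most of the latter, with a median of 83.5 CPM.

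Atoh1 was found in the induced library alone, at a low level. Atoh1 (ENSMUSG00000073043, chromosome 6, 64729125 to 64731245, plus strand) had 0 UMIs in all kept control cells and 152 UMIs in Plp1_TAT_DTR, 3.01 CPM (2.55 to 3.53), at least 53.8-fold higher against a floor of 3 UMIs over the control cells. It had 22 UMIs in myelinating-Schwann-like cells (9.73 CPM, 6.10 to 14.7), 11 in inner-border/phalangeal-like cells (5.42 CPM, 2.71 to 9.70), 8 in inner-hair-like cells (5.57 CPM, 2.40 to 11.0) and 74 in cells without a name (2.35 CPM, 1.85 to 2.95). Tbx2 (ENSMUSG00000000093, chromosome 11, 85832551 to 85841948, plus strand) was abundant in inner-border/phalangeal-like cells of both libraries, at 412 CPM (376 to 451) in control and 377 CPM (351 to 405) in Plp1_TAT_DTR, a ratio of 0.915 (0.815 to 1.03). In myelinating-Schwann-like cells Tbx2 was lower in Plp1_TAT_DTR, 29.2 against 63.0 CPM, a ratio of 0.463 (0.348 to 0.609). Over all cells Tbx2 was higher in Plp1_TAT_DTR, 94.97 against 50.98 CPM, a ratio of 1.86 (1.78 to 1.95), as it was in cells without a name, 83.0 against 44.9 CPM, a ratio of 1.85 (1.72 to 1.98). Within Tbx2-rich named classes the ratio was lower, at 0.850 (0.725 to 1.0004) in Reissner's-membrane-like and 0.857 (0.670 to 1.11) in melanocyte-like cells. Both classes had larger shares in Plp1_TAT_DTR, so the value over all cells can in part reflect the mix of cells. Neither class is among the cells without a name, so these shares do not bear on the rise there. In Deiters/pillar-like cells Tbx2 was higher in Plp1_TAT_DTR, with 15 against 0 UMIs, at least 3.40-fold. Plp1, the myelin gene whose promoter drives the recombinase, was at 9589 CPM in Plp1_TAT_DTR and 9133 CPM in control myelinating-Schwann-like cells (ratio 1.05, 1.03 to 1.07). It was at 35.5 and 75.8 CPM in inner-border/phalangeal-like cells (ratio 0.468, 0.338 to 0.646). Whether transcripts of the inserted Atoh1 and Tbx2 copies are counted under these genes is not stated. Free RNA in droplets can give a few UMIs to any cell, so the Atoh1 levels by class are not read as expression in each class.

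tdTomato, which the feature list carries as its own entry, was lower in Plp1_TAT_DTR in glia and supporting cells and higher in its inner-hair-like cells. It stood at 2154 CPM (2110 to 2199) in control and 408 CPM (383 to 436) in Plp1_TAT_DTR myelinating-Schwann-like cells. The levels were 3752 CPM (3553 to 3960) and 424 CPM (370 to 483) in satellite-glia-like cells, and 1358 CPM (1292 to 1426) and 192 CPM (174 to 212) in inner-border/phalangeal-like cells. In inner-hair-like cells it was 332 CPM (288 to 381) in control and 531 CPM (494 to 570) in Plp1_TAT_DTR. The outer-hair-like cells of Plp1_TAT_DTR had 17.0 CPM (2.06 to 61.5) from 2 UMIs. The control hair cells also carried Slc1a3 and Gjb2 of supporting cells, at a median per cell of 682 CPM for both together against 0 in the inner-hair-like cells of Plp1_TAT_DTR. In summed UMIs the latter still held Slc1a3 at 232 CPM and Gjb2 at 217 CPM, against 455 and 658 CPM in control. The deepest of these Plp1_TAT_DTR barcodes, at 106090 UMIs, held 210 of the 333 Slc1a3 UMIs and 143 of the 312 Gjb2 UMIs. Slc1a3 was found in 15 and Gjb2 in 20 of these 49 cells, so the summed levels rest on few of them. tdTomato was looked at after the data were seen, and which allele gives tdTomato in Plp1_TAT_DTR is not stated in its genotype label.

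**Figure D2:**
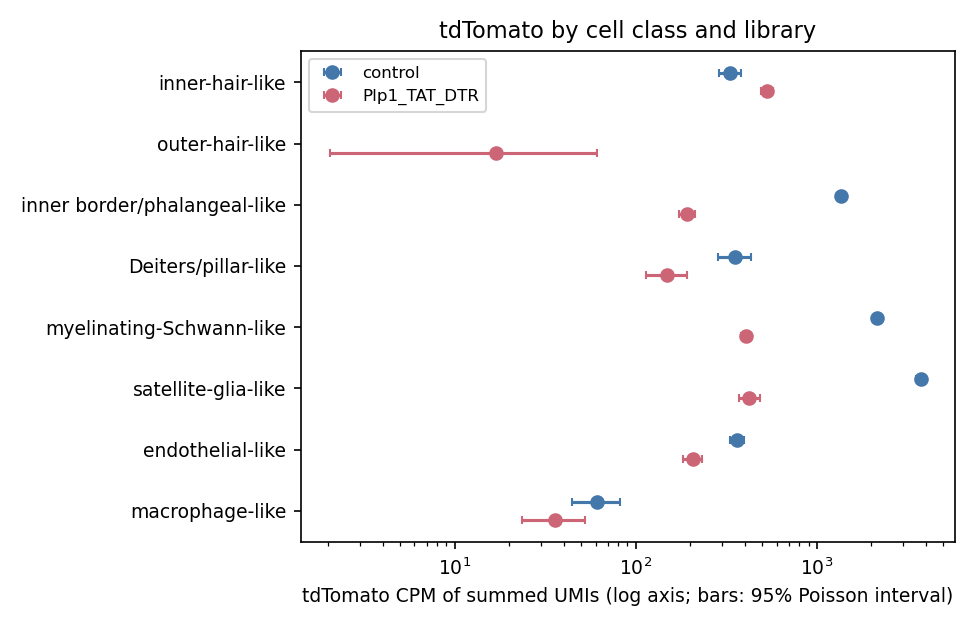
tdTomato level in CPM of summed UMIs (horizontal log axis) by cell class and library, with exact Poisson intervals as bars. The level is lower in Plp1_TAT_DTR than in control in each class drawn except inner-hair-like cells, at 531 against 332 CPM, and no outer-hair-like cell was kept in control.

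Hair-cell-like cells of Plp1_TAT_DTR were compared with inner-border/phalangeal-like cells of control, the cell type that new inner hair cells are proposed to come from, and differed across the hair cell and supporting cell programmes. Otof (ENSMUSG00000062372, chromosome 5, 30367062 to 30461932, minus strand) had 5483 UMIs against 0, at least 1381-fold higher, and Slc17a8 (ENSMUSG00000019935, chromosome 10, 89574020 to 89621253, minus strand) had 2306 against 0, at least 581-fold higher. Inner hair cell genes were higher for 6 of 7 members. Their median log2 ratio was 9.11, or 7.79 with the 3 genes at 0 set to their bound, against 95% of random lists between -1.21 and 1.21. Calb2 was 593-fold higher (288 to 1476) and Atp2a3 1646-fold (295 to 65049, from 1 UMI on the control side), while Tbx2 was lower, at a ratio of 0.421 (0.362 to 0.490). Genes of inner border and phalangeal cells were lower for 10 of 10 members, with a median log2 of -2.99. Slc1a3, a glutamate transporter (ENSMUSG00000005360, chromosome 15, 8634124 to 8710764, minus strand), had a ratio of 0.103 (0.0920 to 0.116). The gap junction genes Gjb2 and Gjb6 had ratios of 0.0989 (0.0876 to 0.111) and 0.0935 (0.0813 to 0.107).

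The other hair cell lists pointed the same way in that comparison. Mechanotransduction genes were higher for 8 of 9 measured members, at a median log2 of 7.63 (6.23 at the bound), with Cib2 202-fold higher (141 to 299) and Tmc1, a subunit of the transduction channel, at least 178-fold. Hair bundle genes were higher for 18 of 19, at 7.17 (4.68 at the bound), with Espn 396-fold higher (109 to 3273, from 2 UMIs on the control side) and Xirp2 at least 126-fold. Ribbon synapse and exocytosis genes were higher for 11 of 11, at 6.71 (4.99 at the bound), including Cacna1d, the calcium channel of the inner hair cell synapse, at a ratio of 132 (36.3 to 1096) from 350 against 2 UMIs. Hair cell channels were higher for 7 of 8, at 6.01 (3.41 at the bound), and calcium buffers for 7 of 8, at 5.51 (4.62 at the bound). Hair cell transcription factors were higher for 5 of 8, at 4.86 (3.54 at the bound), and outer hair cell genes for 8 of 9, at 4.45 (1.82 at the bound). Pou4f3, a hair cell transcription factor, had 793 UMIs against 0, at least 200-fold higher, and Ikzf2 was lower at a ratio of 0.151 (0.109 to 0.205).

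Among the supporting cell programmes, Notch pathway genes were lower for 11 of 13 at a median log2 of -2.36, with Lfng at a ratio of 0.0921 (0.0670 to 0.124). Tectorial and otic matrix genes were lower for 8 of 9 at -2.44, with Ceacam16 at 0.133 (0.118 to 0.149). Interferon and MHC class I genes stood at -1.88 and phagocytic macrophage genes at -1.45, both outside the range of random lists. Inside that range were immediate early genes at -0.93, myelin genes at -0.83, fibrosis and matrix genes at -0.58, p53 targets at 0.21 and nuclear oxidative phosphorylation genes at 0.47. The genes lower by the largest near bound were Lgals3 (0 against 67 UMIs, at least 29.6-fold lower), Slitrk3 (ratio 0.0284, 0.0129 to 0.0549), Irgm1, Tshz3, Plcd4, 6330411D24Rik, Cd9, Cpa6, Lum and Slc44a3. Those higher were, besides Otof, Slc17a8, Calb2 and Atp2a3, the calcium buffers Ocm (2822-fold, 506 to 111509, from 1 UMI) and Pcp4, a calmodulin regulator (548-fold, 327 to 1003), with Lhfpl5, Kcna10, Syt14 and Apba1. Of the 3736 Ocm UMIs, 3690 lay in the 8 outer-hair-like cells, as did 36 of 36 of Slc26a5 and 181 of 191 of Lbh, so the levels of these genes rest on those cells. Genes of the lists took no part in the clustering, whereas others such as Pcp4 and Slitrk3 could help to form these classes. Some list genes did serve to name the classes. Slc1a3, Sox2, Gjb2, Gjb6, Otog and Otogl named the inner-border/phalangeal-like cluster. Otof, Pou4f3, Gfi1 and Cib2 were among the markers that named the hair-cell-like cluster. The directions of these genes therefore partly restate the naming. The comparison sets 57 cells of 1 library against 72 of another.

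The same contrast within the Plp1_TAT_DTR library gave the same directions for these programmes. The same limit from the naming of the classes holds here. Inner hair cell genes were higher for 6 of 7 members, at a median log2 of 8.09 (7.88 with 2 genes at their bound), with Slc17a8 602-fold higher (258 to 1856) and Otof 1432-fold (613 to 4411). Ocm, at 3736 against 0 UMIs, was at least 1626-fold higher. Genes of inner border and phalangeal cells were lower for 9 of 10, at -2.86, with Slc1a3 at a ratio of 0.125 (0.111 to 0.140) and Epyc, a matrix proteoglycan, at 0.0791 (0.0630 to 0.0982). Hes1, a Notch target, was at 0.0785 (0.0563 to 0.107), and Psme1, an interferon-induced proteasome gene, had 0 against 72 UMIs. Atoh1, with 9 UMIs in hair cells and 11 in inner-border/phalangeal-like cells, had too few counts to compare (ratio 1.07, 0.391 to 2.84). Tbx2 was lower in hair cells at 0.461 (0.3996 to 0.5300). Between the same classes of control, 10 against 72 cells, the inner hair cell list stood at 9.27 (8.32 at the bound) and the inner border and phalangeal list at -1.42, while the median over all tested genes stood at -0.15.

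The subclusters, formed without the list genes, divided the hair cells of Plp1_TAT_DTR into inner-hair-like and outer-hair-like cells. Their names came from the inner list without Tbx2 and the outer list without Bcl11b. The list levels below therefore partly restate the naming. The 49 inner-hair-like cells held the inner hair cell list at 7910 CPM (7766 to 8057) and the outer list at 107 CPM (90.3 to 125), an inner to outer ratio of 74.3 (63.3 to 87.7). The 8 outer-hair-like cells held them at 562 CPM (434 to 715) and 36044 CPM (34966 to 37146). The 10 control hair cells held the inner list at 6532 CPM (6331 to 6739) and the outer list, mostly Ocm, at 921 CPM (847 to 1001), a ratio of 7.09 (6.49 to 7.76). Without Ocm the outer list stood at 187 CPM (154 to 225) in control hair cells and 74.5 CPM (61.0 to 90.0) in inner-hair-like cells of Plp1_TAT_DTR. Between both kinds of cell in Plp1_TAT_DTR, Atp2a3, a calcium pump, had 2179 against 0 UMIs, at least 59.4-fold higher in inner-hair-like cells. Igfbp5 was 361-fold higher (99.9 to 2982) from 2 UMIs on the other side, and Tbx2 had 270 against 0 UMIs, at least 7.36-fold higher. Slc26a5 had 0 against 36 UMIs, at least 147-fold lower, Calb1 0 against 67, at least 273-fold lower, and Chrna10, a subunit of the efferent acetylcholine receptor, 1 against 74. Ribbon synapse genes were higher in inner-hair-like cells for 8 of 11, at a median log2 of 1.43 (0.91 at the bound). Myelin genes were lower for 6 of 6, at -5.26, and Plp1 stood at 400 CPM (294 to 532) in the outer-hair-like cells, in 4 of 8 of them.

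Hair-cell-like cells of Plp1_TAT_DTR resembled those of control in inner hair cell genes and differed from them in a set of genes nearly absent from control. They also fell mostly into other subclusters. Inner-hair-like subclusters 0, 1 and 6 held 18, 14 and 5 cells of Plp1_TAT_DTR and 0 of control. Subclusters 3, 4 and 5 held 1, 4 and 5 control cells, with 7, 4 and 1 of Plp1_TAT_DTR. Median depth was 24790.5, 28782.5 and 33679 UMIs in subclusters 0, 1 and 6, and 28295, 89715.5 and 43069 in subclusters 3, 4 and 5. Depth can therefore take part in this division, which was not tested. The inner hair cell list stood at a median log2 of 0.13 between the libraries (counting interval 0.05 to 0.22), inside the range of random lists. Slc17a8 was at a ratio of 1.09 (1.01 to 1.19), Calb2 at 1.10 (1.04 to 1.16), Otof at 1.35 (1.28 to 1.43) and Tbx2 at 0.814 (0.658 to 1.01). The 10 genes higher by the largest near bound were Foxj1 (ENSMUSG00000034227, chromosome 11, 116330704 to 116335399, minus strand), a transcription factor of motile cilia, with 196 against 0 UMIs, at least 25.6-fold higher, and Dupd1, Mylk4, Hs3st6, Rbfox3, Clec2l, R3hdml, Tspan2, Tafa3 and Atp8a2. Dupd1 had 181 against 0 UMIs, at least 23.6-fold, and Mylk4, a myosin kinase, 162 against 0, at least 21.2-fold. Rbfox3, a splicing factor best known from neurons, had 227 against 2 UMIs, a ratio of 44.5 (12.2 to 370). The median log2 over these 10 genes was 6.16, or 4.51 with the 6 genes at 0 set to their bound. Per cell, the 10 genes together reached 0 to 37.9 CPM in control hair cells and a median of 1137 CPM in inner-hair-like cells of Plp1_TAT_DTR, 48 of 49 of which lay above the highest control cell. So did 8 of 8 outer-hair-like cells, at a median of 225 CPM, with 24 UMIs of Atp8a2, 1 each of Hs3st6 and Tspan2, and 0 of the other genes. The genes were chosen in these same cells, so these counts restate that choice.

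Hair cell function genes and supporting cell genes moved apart in that comparison. Mechanotransduction genes stood at a median log2 of 0.80, with Lhfpl5 at a ratio of 2.72 (2.39 to 3.10) and Tmc1 at 2.33 (1.91 to 2.85). Ribbon synapse genes stood at 0.51, higher for 11 of 12, with Cabp2 at 2.04 (1.84 to 2.28), and hair bundle and nuclear oxidative phosphorylation genes at 0.42, each at or above the upper end of the random range. Inner border and phalangeal genes were lower for 9 of 10, at -1.55, and Notch genes for 9 of 13, at -1.16, with Gjb2 at 0.305 (0.262 to 0.354) and Id2 at 0.257 (0.212 to 0.311). The genes lower by the largest near bound were Fgfr3, a receptor of Deiters and pillar cells, with 1 against 46 UMIs (ratio 0.00852, 0.000211 to 0.0499), Lgals3 and Nrgn, each with 0 against 14 UMIs, Irgm1, Anpep, Aox2, Lum, Mdm1, Plk1 and Bace2. Outer hair cell genes stood at 1.49 (1.02 to 1.81) with all hair cells and at -2.06 with inner-hair-like cells alone, so their direction came from the 8 outer-hair-like cells. The control side held 10 cells, 4 of them above 60000 UMIs against 1 in Plp1_TAT_DTR. The control cells also carried supporting-cell RNA, at a median per cell of 682 CPM of Slc1a3 and Gjb2 together. In inner-hair-like cells of Plp1_TAT_DTR that median was 0. Such RNA in the control barcodes can add to both directions above, which was not tested for these lists.

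**Figure D3:**
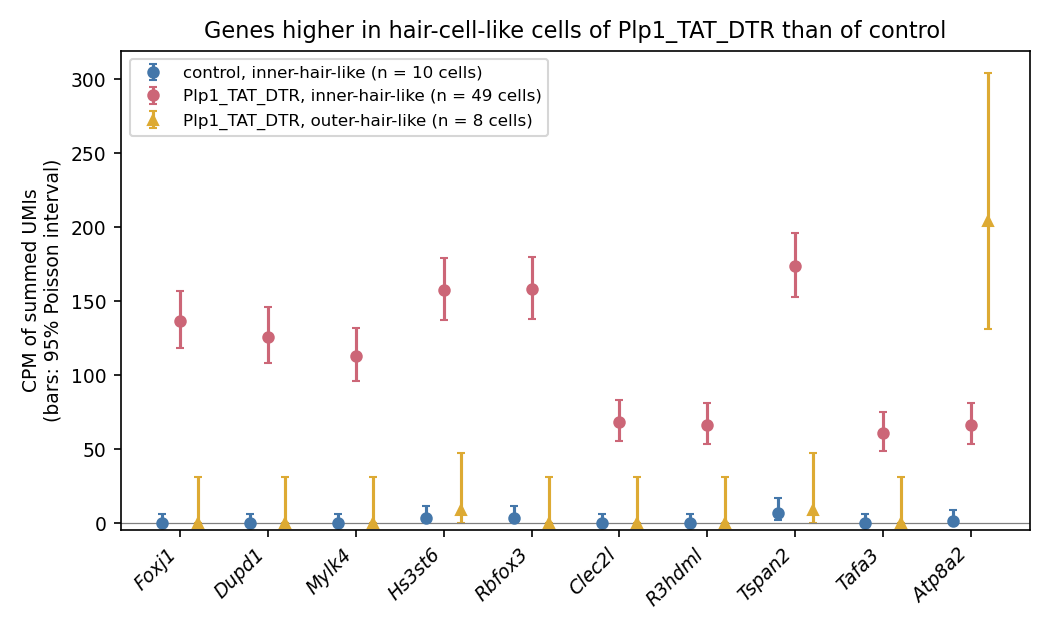
Level in CPM of summed UMIs (vertical axis) of the 10 genes higher in hair-cell-like cells of Plp1_TAT_DTR than of control, for inner-hair-like cells of both libraries and outer-hair-like cells of Plp1_TAT_DTR, with exact Poisson intervals as bars. Inner-hair-like cells of Plp1_TAT_DTR reach 60.6 CPM for Tafa3 to 173 CPM for Tspan2, and Atp8a2 alone is higher in outer-hair-like cells, at 204 CPM.

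Inner-border/phalangeal-like cells of Plp1_TAT_DTR had slightly lower levels of most of their own markers, and lower tdTomato, Lgals3 and myelin transcripts. The inner border and phalangeal list stood at a median log2 of -0.23 (-0.30 to -0.17), lower for 9 of 10 genes and outside the range of random lists, with Slc1a3 at a ratio of 0.830 (0.788 to 0.874) and Gjb6 at 0.634 (0.596 to 0.676). Higher genes included Emcn (11.6-fold, 3.77 to 57.7, from 3 UMIs), Mia, a secreted cartilage protein (2.75-fold, 2.27 to 3.35), the androgen receptor Ar, Lamb3, Sh2d6, Xlr3b and, with 0 UMIs in control, Farp1, Gm16867, Slc45a3 and Loxl2. Lower genes were Lgals3 (ratio 0.0345, 0.00915 to 0.0926), tdTomato (0.142, 0.126 to 0.158), Mrap2, Cngb1, Zfp990, Mt1, Atp1a3, Rnase1 and the myelin genes Mpz (0.145, 0.0744 to 0.263) and Pmp22. Myelin genes were lower for 6 of 7, at -1.09, and nuclear oxidative phosphorylation genes were higher for 9 of 11, at 0.22, just outside the random range. Myelinating-Schwann-like cells, which Mpz and Mbp lead, had a smaller share in Plp1_TAT_DTR, so less free RNA can lower myelin transcripts here, which was not tested. The interferon list stood at -0.25 (-0.79 to 0.02) and Notch genes at -0.12 (-0.23 to 0.02), both inside the random range.

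Interferon response and MHC class I genes were lower in Plp1_TAT_DTR in each of the 8 other classes and clusters with at least 100 cells per library. The list's median log2 ran from -1.55 in cluster 2, an unnamed cluster with Ccl11 and Dcn among its leading genes, to -0.38 in endothelial-like cells, each below the range of random lists. It was -0.51 in myelinating-Schwann-like cells, lower for 10 of 11, with Isg15 at a ratio of 0.338 (0.251 to 0.450). It was -1.09 in satellite-glia-like cells, lower for 12 of 12, with Ifit1, an antiviral effector, at 0.237 (0.170 to 0.326). Ifit1 was at 0.153 (0.125 to 0.186) in cluster 1 and 0.0973 (0.0862 to 0.110) in cluster 2. Ifi27l2a, another interferon-induced gene, was at 0.0125 (0.00257 to 0.0368) in cluster 6 from 3 UMIs, 0.0400 (0.0128 to 0.0957) in cluster 7 and 0.0206 (0.0106 to 0.0363) in cluster 3. H2-D1 went the other way in clusters 1 and 6, at 1.22 (1.11 to 1.34) and 1.32 (1.14 to 1.53). Genes of the MHC class I family have similar sequences, and counts could be split between them.

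Other lists varied by class between the libraries. Immediate early genes were higher in endothelial-like cells, at a median log2 of 0.35 with 11 of 13 higher, in myelinating-Schwann-like cells, at 0.28, and in cluster 2, at 0.21, and lower in cluster 6, at -0.15, just outside the random range. Fibrosis and matrix genes stood at 0.54 in cluster 1, led by Notum and Fn1, and 0.63 in cluster 6, led by Fst and Abcc9. Inflammatory signals ran from -1.09 in satellite-glia-like cells to 0.61 in cluster 2. p53 targets ran from -0.04 to 0.17, with none of their medians outside the random range. Myelin genes were below 0 in 7 of 8 comparisons, down to -1.46 in cluster 3. Plp1 itself was higher in endothelial-like cells (ratio 2.55, 1.71 to 3.86), fibrocyte-like cells (14.8, 3.98 to 124, from 2 control UMIs) and Deiters/pillar-like cells (16.5, 5.44 to 82.0, from 3 control UMIs). Plp1 was lower in pericyte-like cells (0.0645, 0.0288 to 0.127), marginal-like cells (0.173, 0.107 to 0.280, from 34 UMIs in 3 control cells) and macrophage-like cells (0.199, 0.0804 to 0.429). It was lower too in cells without a name (0.467, 0.441 to 0.494). Less free RNA from fewer Schwann cells would not give the rises but could give the falls, which was not tested. Myelin genes stood at 0.08 in myelinating-Schwann-like cells, their own class, where Mpz was at a ratio of 1.22 (1.21 to 1.24) and Mbp at 0.843 (0.826 to 0.860). Of the sex-linked list, Uty had 2 UMIs in control and 0 in Plp1_TAT_DTR, Eif2s3y 0 and 1, Ddx3y and Kdm5d 0 in both, and Xist is not among the features, so the sex of the animals was not read from them.

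Single genes set the libraries apart in several of these classes. In myelinating-Schwann-like cells Dnase1 had 36 against 0 UMIs, at least 22.2-fold higher in Plp1_TAT_DTR, Coch, a matrix protein of fibrocytes, was 15.5-fold higher from 619 against 74 UMIs, and Ccn3 was lower at 0.0874 (0.0611 to 0.122). In endothelial-like cells Coch was 5.02-fold higher (3.91 to 6.51) and Mfsd2a, a lipid transporter of barrier vessels, was at 0.177 (0.125 to 0.246), with the mural cell genes Acta2 and Tagln at 0.100 (0.0312 to 0.249) and 0.165 (0.0756 to 0.324). In satellite-glia-like cells Tyrp1 was 23.6-fold higher (6.31 to 199) from 2 control UMIs and Nrn1 was at 0.109 (0.0727 to 0.159). In cluster 3 the bone gene Bglap had 0 against 1123 UMIs, at least 318-fold lower. Spp1 was 4.71-fold higher (4.10 to 5.42) in cluster 1 and 5.04-fold (4.54 to 5.60) in cluster 7, but lower in endothelial-like cells at 0.514 (0.452 to 0.583). Transcripts of other cell types, such as Coch and Tyrp1 in glia, can reach a barcode as free RNA, and the endothelial-like class joins 2 clusters.

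**Figure D4:**
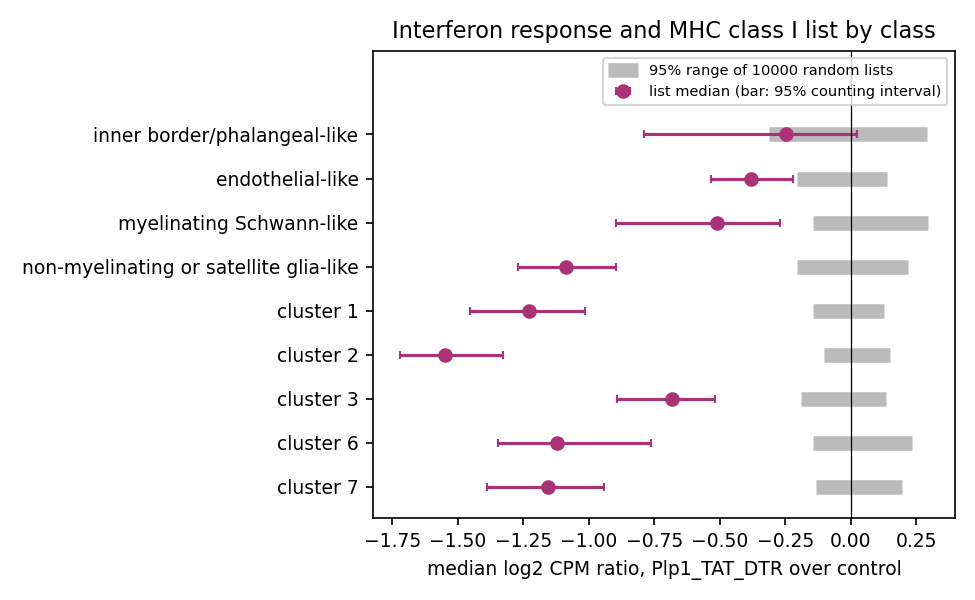
Median log2 CPM ratio, Plp1_TAT_DTR over control, of the interferon response and MHC class I list (points, with counting intervals as bars) in each class or cluster, beside the range of 95% of 10000 random lists matched on expression (grey). The median lies below the grey range in 8 of the 9 comparisons and inside it for inner-border/phalangeal-like cells.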

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

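All tests in this part were chosen after the results they concern had been seen, and each rests on 1 library per group.

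The 10 genes higher in hair cells of Plp1_TAT_DTR (Foxj1, Dupd1, Mylk4, Hs3st6, Rbfox3, Clec2l, R3hdml, Tspan2, Tafa3 and Atp8a2) had a median log2 ratio of 6.16, or 4.51 with genes at 0 set to their bound. Outer hair cells in the Plp1_TAT_DTR class are argued against as the cause, since inner-hair-like cells alone gave 6.28, or 4.62 at the bound. Free RNA of that library is argued against for the 10 genes as a set. Barcodes outside the class held a median over the genes of 0.0236 of the UMIs per barcode of inner-hair-like cells. For single genes this ran from 0 to 0.447, so the test is weaker for some of them. Clec2l was among the 10 leading genes of a spiral-ganglion-neuron-like cluster, and Dupd1 among those of the unnamed cluster 31. Supporting-cell RNA diluting the control hair cells is argued against because the 10 hair cell markers had a median log2 ratio of 0.29, from -0.88 to 1.49. With 10 genes chosen on a random part of the hair cells and the other cells scored, then the reverse, 49 of 49 inner-hair-like cells and 0 of 8 outer-hair-like cells of Plp1_TAT_DTR lay above the highest control cell scored. Both parts come from the same libraries, so any difference between the libraries recurs in each. The genes chosen shared 7 and 6 with the 10 above. The highest control cells reached 387 and 179 CPM, against 37.9 CPM for the 10 genes above, which bears on the 0 of 8. New inner hair cells made from supporting cells cannot be told apart by this split from a response of existing inner hair cells or from another difference between the animals, as each group is 1 library.

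Interferon and MHC class I genes had a median log2 ratio below 0 in 8 of the 8 comparisons of other classes between the libraries. A candidate source is free RNA of cluster 21, which held 82 control cells and 7 of Plp1_TAT_DTR and was led by Plac8, Ifit1, Ifit3, Rsad2 and Isg15. In myelinating-Schwann-like cells such RNA had room for at most 7.68% of the list's control UMIs, limited by Ifit1, against a control excess of 22.9%, which argues against it as the whole cause there. In endothelial-like and satellite-glia-like cells the smaller ratio of that room to the excess was 0.902, so it stays open, and the split by class was made after the values were seen. Damage and induction in Plp1_TAT_DTR cannot be told apart from an immune state of the control animals, as each group is 1 library.

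Atoh1 UMIs appeared in many classes of Plp1_TAT_DTR and in none of control. Inner-border/phalangeal-like barcodes held 3.77 times as many per barcode (1.84 to 6.97) as other barcodes outside the hair-cell class, but by CPM the ratio was 1.93 (0.938 to 3.56), so free RNA stays open. Transcription in the classes that express Plp1 stays open too. The classes with Plp1 at or above 100 CPM (Schwann-like, satellite-glia-like, melanocyte-like, neuron-like and Deiters/pillar-like cells) held 1.20 times the Atoh1 UMIs per barcode (0.671 to 2.22) and 1.70 times the CPM (0.951 to 3.15) of the other named classes, without hair-cell-like and inner-border/phalangeal-like cells. With inner-border/phalangeal-like cells among the other classes the ratios were 0.881 (0.533 to 1.47) and 1.37 (0.831 to 2.30). The split rests on Plp1 at postnatal day 42, whereas tamoxifen was given at days 0 and 1. In control, inner-border/phalangeal-like cells had 75.8 CPM of Plp1 and 1358 CPM of tdTomato, and neuron-like cells 476 and 105 CPM. The split need not follow recombination, so it cannot decide whether the induced copies are transcribed.

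The direction of 3 genes between hair-cell-like and inner-border/phalangeal-like cells was opposite in the libraries, a difference that was not tested. The log2 ratio of Mpz was 3.12 in Plp1_TAT_DTR and -1.97 in control, that of Pmp22 was 2.09 and -1.81, and that of tdTomato was 1.35 and -2.03. In Plp1_TAT_DTR, 78 of 96 Mpz UMIs and 23 of 24 Pmp22 UMIs of the hair cells lay in the 8 outer-hair-like cells, a kind of which control kept none. tdTomato, which no planned comparison used, was also above the control hair cells in the inner-hair-like cells of Plp1_TAT_DTR, at a CPM ratio of 1.60 (1.37 to 1.88).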

How the results depend on the processing

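The limit of 60000 UMIs, inner-hair-like cells alone, the outer list without Ocm and the gate of 8 markers were chosen after the data were seen. Of 210 alternative values of 18 results, 181 lay within the interval of the value reported, 26 lay outside it with the same sign and 3 lay outside it with the opposite sign. The log2 ratio of Tbx2 in inner-border/phalangeal-like cells, negative as reported, reached 0.0212 at its highest alternative, within its interval. The 10 genes higher in Plp1_TAT_DTR hair cells were tried singly only with inner-hair-like cells, with and without the limit of 60000 UMIs, and these 20 values lay within their intervals. The gate of 3 hair cell markers took 585 control and 633 Plp1_TAT_DTR cells, mostly outside the hair cell cluster, shares of 15.04% and 13.53%. It gave an inner list at 5.61 and an inner border list at -2.72 against control and -2.58 within Plp1_TAT_DTR, log2 of inner over outer UMIs 3.88 in control and 2.63 in Plp1_TAT_DTR. Between hair cells the inner border list reversed to 0.93 and the 10 genes stood at 1.11. Without a mitochondrial limit, which let in 2 outer-hair-like control cells, log2 inner over outer in control was 1.94 and the outer list between hair cells 0.65. With the mean of the cells' own CPM, Atoh1 stood at 4.12 CPM, the inner border list at -3.94, -3.68 and -2.09 against control supporting cells, within Plp1_TAT_DTR and between hair cells. It put the inner list within Plp1_TAT_DTR at 8.997, log2 inner over outer in Plp1_TAT_DTR at 0.37 and the outer list between hair cells at 2.47. CPM without mitochondrial, ribosomal protein and haemoglobin genes gave Atoh1 3.77, by its smaller total, and a minimum of 30 UMIs gave log2 inner over outer 3.05 in control. Between hair cells, inner-hair-like cells alone reversed the outer list to -2.06, by leaving out outer hair cells. Hair cells up to 60000 UMIs gave the outer list 2.24, inner border list -1.27 and the 10 genes 4.95, and inner-hair-like cells up to that limit gave -1.19 (reversed), -1.16 and 5.05. Other values of log2 inner over outer are over list genes with at least 10 UMIs in that library's hair cells, 1.38 in Plp1_TAT_DTR and 2.85 in control as first counted, which leaves Kcnq4 and Lmod3 out in control. Without Ocm too, it was 4.13 in Plp1_TAT_DTR and 5.26 in control. The cause of the other shifts was not tested.

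A mitochondrial limit of 10% left no hair cell cluster, as 0 of 10 control and 5 of 57 Plp1_TAT_DTR hair cells passed it, and no limit or a resolution of 0.5 left inner border and phalangeal cells unnamed, so these gave no such values. Median-of-ratios scaling gives no level of a single group. The 10 control hair cells limit what their comparisons can resolve. No paired analysis was possible because each group has 1 library, and leaving a library out was not possible.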

Other observations

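The genes in this part were chosen after the data were seen. The 10 control hair cells carried Ocm, a calcium buffer most abundant in outer hair cells, at 447 UMIs, with 10 UMIs of Chrna10, 18 of Lbh and 22 of Strip2, and 0 of Slc26a5 and of Calb1. In inner-hair-like cells of Plp1_TAT_DTR, at 49 cells, Ocm had 46 UMIs and Strip2 had 45. Fgf8, a growth factor of inner hair cells, had 0 UMIs in control hair cells and 30 in inner-hair-like cells of Plp1_TAT_DTR, 20.9 CPM (14.1 to 29.8).

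Several genes outside the lists were higher in Plp1_TAT_DTR in more than 1 class. Ptgds, a prostaglandin synthase, was 8.31-fold higher (6.95 to 9.97) in myelinating-Schwann-like cells, 6.73-fold (3.39 to 15.2) in satellite-glia-like cells, 5.27-fold (4.595 to 6.069) in cluster 1 and 6.28-fold (4.082 to 10.02) in cluster 7. It was lower in cluster 3 at a ratio of 0.0480 (0.0397 to 0.0575). Ptgds was among the 10 leading genes of the fibrocyte-like cluster, which made up 1.05% of control and 2.76% of Plp1_TAT_DTR cells. Free RNA can therefore add to the rises, which was not tested. Gm16867, a predicted gene, had 25 against 0 UMIs in myelinating-Schwann-like cells, 64 against 0 in cluster 7 and 135 against 1 in cluster 1. Ccn3, a matricellular protein, was lower in cluster 1 at 0.173 (0.156 to 0.191), in cluster 6 at 0.146 (0.0921 to 0.220) and in cluster 7 at 0.216 (0.172 to 0.268).

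Tectorial and otic matrix genes between the libraries had a median log2 of 0.81 in cluster 6 and 0.69 in cluster 1. Ceacam16, a tectorial membrane gene, was at 220 CPM in hair cells of Plp1_TAT_DTR and 29.6 CPM in those of control, a ratio of 7.42 (4.63 to 12.7), opposite to the list's median of -1.49 in that comparison. Ceacam16 was among the 10 leading genes of the unnamed clusters 4 and 8. These made up 2.06% and 2.01% of control cells, and 7.65% and 4.04% of Plp1_TAT_DTR cells. Free RNA can therefore add to this rise, which was not tested.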
